A study of Oryza sativa with 16 samples.

How the data were processed

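Strips of 2 cm from leaves of 6-week-old rice plants of the indica cultivar Pusa Basmati 1, grown in a greenhouse under natural day and night near 28 °C, were kept overnight in sterile water and then in phytosulfokine in plates of 6 wells. RNA was extracted from wild type and receptor knockout strips and sequenced as strand-specific libraries, with 2 libraries for each of the 8 groups of genotype and time. The labels do not say whether the 2 libraries of a group came from separate plants. Each deposited table holds FPKM (fragments divided by transcript length and by library size) of 1 library, made by the authors with Trimmomatic, HISAT2 and Cufflinks 2.2.1 according to the submitters' processing notes, with the lower and upper bounds of a 95% interval in FPKM. The deposited FPKM values were not scaled between libraries. The genome build is not given in the sources used here, and coordinates are those of the files, with the start counted from 1.

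The tables could not be joined by identifier, because transcripts were assembled separately in each library and many loci carry an assembly number in place of a rice locus identifier. Rows were therefore joined by position: a locus was kept when every library had exactly 1 row that overlapped the most common interval by at least 0.8 of both lengths. This gave 28105 loci, of which 16629 carried an identifier in at least 1 library, and these held 63.0% to 68.3% of the FPKM of a library. Another 2482 intervals had more than 1 row in some library and were left out, so genes at such places have no value in the comparisons. Of the tested loci, those overlapped by another row with a value above 0 were marked, since the tables give no strand and reads could be shared. Planned summing of rows by identifier was replaced by this joining, and the planned lists by product text could not be used, since neither the files nor the reference give product text for these identifiers. The lists of other cell types, hypoxia and handling among them therefore have no result.

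In KO 2 h replicate 1 every row after position 19174055 of chromosome 10, on chromosomes 11 and 12 and on unplaced contigs was exactly 0, 12125 rows in all. In the other 15 libraries 1371 joined loci there had a median of at least 1, so these values were set to missing, and the KO 2 h mean of such a locus is 1 library, whose spread in the tests is taken from the other groups. Depth was estimated from the deposited intervals as 8830000 to 10840000 fragments per library, a lower bound that covers counting error only.

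FPKM were scaled per library by the median ratio to the geometric mean over loci with at least 1 in all libraries, with factors of 0.920 to 1.09. Loci with a Cufflinks status other than OK were left out, and 13095 loci with scaled FPKM of at least 1 in at least 2 libraries were tested on log2(scaled FPKM + 1). One model of the 8 group means was fitted in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), and a locus was called when its two-sided moderated test had a Benjamini-Hochberg adjusted p below 0.05 over all loci of the comparison. There were 14 comparisons: 3 times against 0 min in each genotype, KO against WT at each time and over all times, and 3 genotype by time terms. These choices were made before the data were examined, apart from the joining by position, the missing part and what is named as added below. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

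Genes were named by a fixed rule: for each comparison the 6 largest rises and falls with an informative name, up to 4 members of each fixed list with the smallest adjusted p, and every phytosulfokine receptor or precursor gene. The files pair no names with identifiers, so the first part gave no gene, and loci of the fixed lists alone are named; more than 4 members of a list are named in places, and 7 other identifiers were picked after their values were seen. List names were written down from general knowledge before the data were examined, under a rule that a name would be printed only if the files or the reference gave it. That rule was relaxed, because the reference holds another assembly without these identifiers and knows some of the genes under other names. Of 66 listed loci 32 joined and 45 names were found in the reference, 44 of them on the chromosome that the identifier states. All 33 pairs of such loci on a chromosome were in the same order, and all 22 spans compared were within 20%, with a median ratio of 0.981. The exception is CYP76M7, a name that the reference puts on another chromosome, so its name is doubtful. No name of PSKR1, WRKY45, WRKY28, WRKY70, WRKY69, PR1b, JIOsPR10, PR4, the LHCB loci, FKF1 or LHCA1 was found in the reference, and these names rest on general knowledge alone.

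The loci tested were ELF3 (Os06g0142600) and PCL1 (Os01g0971800) of 10 clock genes, PSKR1 (Os02g0629400), and TIFY11a (Os03g0180800), TIFY11b (Os03g0181100), TIFY11c (Os03g0180900), TIFY11e (Os10g0391400) and TIFY9 (Os04g0395800) of 9 JAZ repressors. AOS2 (Os03g0225900) and AOC (Os03g0438100) stood for 7 genes of jasmonate synthesis, and WRKY45 (Os05g0322900), WRKY76 (Os09g0417600), WRKY28 (Os06g0649000), WRKY70 (Os05g0474800) and WRKY69 (Os08g0386200) for 10 WRKY factors. PR1b (Os01g0382000), JIOsPR10 (Os03g0300400) and PR4 (Os11g0592200) stood for 6 pathogenesis-related genes, CPS4 (Os04g0178300), CYP76M7 (Os02g0569900) and CYP99A3 (Os04g0178400) for 8 of diterpenoid phytoalexin synthesis, and LHCB1 (Os01g0600900), LHCB1b (Os09g0346500) and LHCB2 (Os03g0592500) for 7 of light harvesting. EXPA2 (Os01g0823100), EXPB3 (Os10g0555900), EXPB4 (Os10g0556100) and EXPB7 (Os03g0102700) stood for 8 expansins. Lists with at least 5 tested members, JAZ and WRKY, were tested with camera at a preset correlation of 0.01, adjusted over the 2 lists of a comparison, and again with an estimated correlation and with fry, which tests whether the loci of a list move one way on balance and does not compare them with other loci. The estimated correlations were -0.14 for JAZ and -0.039 for WRKY, both below the preset value. The fits with them therefore do not check for a stronger correlation between the loci of a list.

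The calling was tested on simulated data, in which 200 loci were changed, drawn from loci with a mean scaled FPKM of at least 5. Noise was drawn independently for each locus and library, with the spread fitted here. The recovered shares therefore do not cover lower loci. The false shares and the camera shares do not cover spread between plants or loci that vary together. In a KO 30 min comparison of 12454 loci 43.3% of 1.5-fold, 82.1% of 2-fold and 93.9% of 4-fold changes were recovered and 3.9% of the calls were false. Over all times the shares were 91%, 97% and 100%, with 5.9% of the calls false. Of 200 sets of 5 unchanged loci 3% passed camera at an unadjusted p below 0.05, and all 50 raised sets did. Only 200 loci were changed there, whereas 2040 loci were called at 30 min in KO and 7146 in WT. Camera compares a list with the other loci, so its shares do not carry over to comparisons where many other loci move.

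Other settings were FPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter on low values, loci of any Cufflinks status, limma's library weights, a block for the library marked as a replicate in its title, the libraries compared alone, and leaving out each library in turn. Alternatives chosen after seeing the data were overlaps of 0.5 and 0.95, the zeros of the missing part kept, the 30 min libraries as the baseline, and, for KO against WT over all times, the fit without the 0 min libraries and with group means as the units.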

Results

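The study asked how transcripts of rice leaves changed in phytosulfokine (PSK), a short sulfated peptide hormone of plants that is perceived by receptor kinases, and how a knockout of its receptor altered that course. RNA sequencing covered leaf strips of the indica cultivar Pusa Basmati 1, wild type (WT) and a line labelled as an OsPSKR knockout (KO), at 0 min, 30 min, 2 h and 4 h in the peptide. Each of the 8 groups had 2 libraries, 16 in all. The deposited 95% intervals of the expression values imply at least 8830000 to 10840000 fragments per library, a lower bound, since library totals were not used here. The tables joined into 28105 loci, and 13095 loci passed the expression filter and were tested. No course without peptide was analysed here, so each change over time is a change with peptide, time in the plate and hour of day together. Values are means of scaled FPKM (fragments per transcript length and library size) ± SD of the 2 libraries of a group, and changes are differences of log2(scaled FPKM + 1), which understate the change of loci near 0. The p-values measure only the spread between libraries of a group, which may be technical.

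The 2 libraries of each group lay close together, with Pearson's r across loci of 0.976 to 0.985. The WT 0 min libraries stood apart from the other groups: their mean r with the other groups was 0.879, against 0.919 to 0.937 for the remaining 7 groups. At 64 loci both WT 0 min libraries were at 4 or more times the level of every other library with a value, and no other group had more than 6 such loci. At 68 loci they were at or under 1/4 of every other library with a value, and no other group had more than 4. Loci are not independent replicates, and no test was run on these correlations. Every change from 0 min in WT, every genotype by time term and the KO difference at 0 min rest on these libraries. The KO difference over all times includes them.

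**Figure D1:**
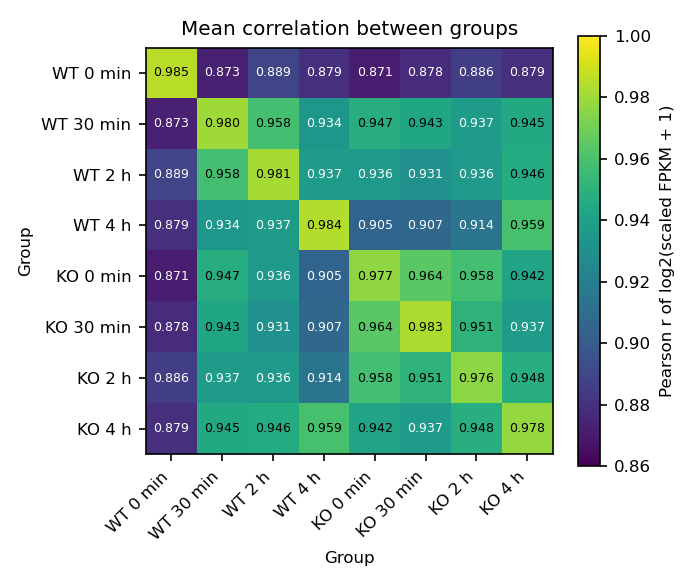
Mean Pearson's r of log2(scaled FPKM + 1) across loci between the libraries of each pair of groups, with the r of the 2 libraries of a group on the diagonal. The WT 0 min libraries have a mean r of 0.879 with the other groups, against 0.919 to 0.937 for each remaining group.

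The labels name the receptor but give neither the edited site nor the kind of edit. PSKR1 (Os02g0629400, chromosome 2, 25176174 to 25179701), the locus listed here for a PSK receptor kinase, was at 1.99 ± 0.29, 2.67 ± 0.083, 2.52 ± 0.091 and 1.53 ± 0.00013 in WT at 0 min, 30 min, 2 h and 4 h. In KO it was at 3.11 ± 0.41, 3.78 ± 0.21, 1.97 ± 0.023 and 2.51 ± 0.26. Against 0 min it was higher in WT at 30 min (log2 0.30, adjusted p = 0.036) and lower in KO at 2 h (-0.46, adjusted p = 0.012). PSKR1 was higher in KO at 0 min (log2 0.46, adjusted p = 0.0044), 30 min (0.38, adjusted p = 0.02) and 4 h (0.47, adjusted p = 0.011), and its difference at 2 h was -0.25 (adjusted p = 0.11). Its course differed between the genotypes at 2 h, with a genotype by time term of -0.70 (adjusted p = 0.0039). A transcript level cannot show whether an edited gene makes protein, so it does not decide whether the line lacks the receptor. Another row of the tables overlaps this locus, and reads could be shared between them.

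In WT leaves, genes of jasmonate signalling and defence regulation rose within 30 min in PSK. All 5 tested JAZ loci of the 9 listed rose, and so they did adjusted over the list alone; JAZ (TIFY) proteins repress jasmonate responses. TIFY11b (Os03g0181100, chromosome 3, 4248884 to 4249820) went from 27.9 ± 2.3 to 194 ± 3.1, a log2 change of 2.76 (SE 0.1, adjusted p = 3.5e-09). TIFY11c (Os03g0180900, chromosome 3, 4236724 to 4238058) went from 2.28 ± 0.51 to 40.1 ± 0.85, a log2 change of 3.66 (adjusted p = 5.9e-09). TIFY11a, beside them on the chromosome, rose from 0.155 ± 0.22 to 6.69 ± 0.85. Of 5 WRKY transcription factors tested, 4 rose, and 5 did adjusted over the list alone. WRKY28 (Os06g0649000, chromosome 6, 26510006 to 26511606) rose from 5.86 ± 0.41 to 29.1 ± 1.6 and WRKY45, a regulator of salicylic acid defence, from 4.5 ± 0.9 to 15.9 ± 2.6. Both jasmonate synthesis loci tested rose, AOS2 (allene oxide synthase) by 1.37 and AOC (allene oxide cyclase) by 1.07 on the log2 scale.

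Tested loci of other lists changed in WT over the same 30 min, though these lists had too few tested members for a list test. All 3 light-harvesting loci rose: LHCB1 (Os01g0600900, chromosome 1, 23607363 to 23608541), a chlorophyll-binding antenna protein, went from 195 ± 9.5 to 1860 ± 32 and LHCB2 from 500 ± 5.2 to 2800 ± 52. Of 3 pathogenesis-related loci 2 rose, PR4 (Os11g0592200, chromosome 11, 22511506 to 22512374) from 0.884 ± 0.29 to 25.6 ± 1.9 and JIOsPR10 from 12.7 ± 0.48 to 31.1 ± 2.7. Of 3 diterpenoid phytoalexin loci, CYP76M7 and CYP99A3 rose by 2.30 and 1.78 and CPS4 fell by 0.41. Of 4 expansins, which loosen cell walls, 3 fell: EXPA2 (Os01g0823100, chromosome 1, 35145517 to 35147323) from 32.1 ± 0.95 to 2.91 ± 0.96, EXPB3 from 20.3 ± 1.9 to 2.32 ± 0.41 and EXPB4 from 9.5 ± 0.55 to 4.5 ± 0.19. Both clock loci tested changed, PCL1 rising from 0.585 ± 0.17 to 4.39 ± 0.058 and ELF3, a part of the evening complex, falling from 32.8 ± 4.9 to 12 ± 0.57. The counts of these lists adjusted over the list alone were equal to those over all loci. Outside the naming rule, which needs an informative name, Os07g0529600 went from 1.81 ± 0.39 to 326 ± 7.2 and Os07g0142900 from 4.93 ± 0.46 to 462 ± 17. Os03g0226200 went from 800 ± 2.4 to a level listed at 0 in both libraries and Os06g0683800 from 121 ± 7.9 to 0.971 ± 0.98. These 4 were chosen after their values were seen. In KO at 0 min Os07g0529600 was at 100 ± 2.1 and Os07g0142900 at 216 ± 10, and Os03g0226200 was at 0.23 ± 0.2 and Os06g0683800 at 0.962 ± 0.032. Outside WT 0 min the highest group means of the last 2 were 0.23 and 2.24. Their falls thus rest on the WT 0 min libraries that stood apart, and a response to the peptide cannot be told from that.

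Over all loci, 7146 of 13095 were called for WT at 30 min, 3749 higher and 3397 lower, and 1413 and 989 of these by 2-fold or more. By camera, limma's test of a set against the other loci, the JAZ list rose (adjusted p = 0.0014, and adjusted p = 0.017 with an estimated correlation), as did the WRKY list (adjusted p = 0.0042, and adjusted p = 0.019 with an estimated correlation). TIFY9, AOC, EXPA2, EXPB3 and EXPB7 lie where another row overlaps the locus. Without scaling between libraries, where the median change of all loci is -0.137 against 0.004 with it, 39.9% of the called loci were higher, against 52.5% with it and 47.3% with quantile normalization.

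**Figure D2:**
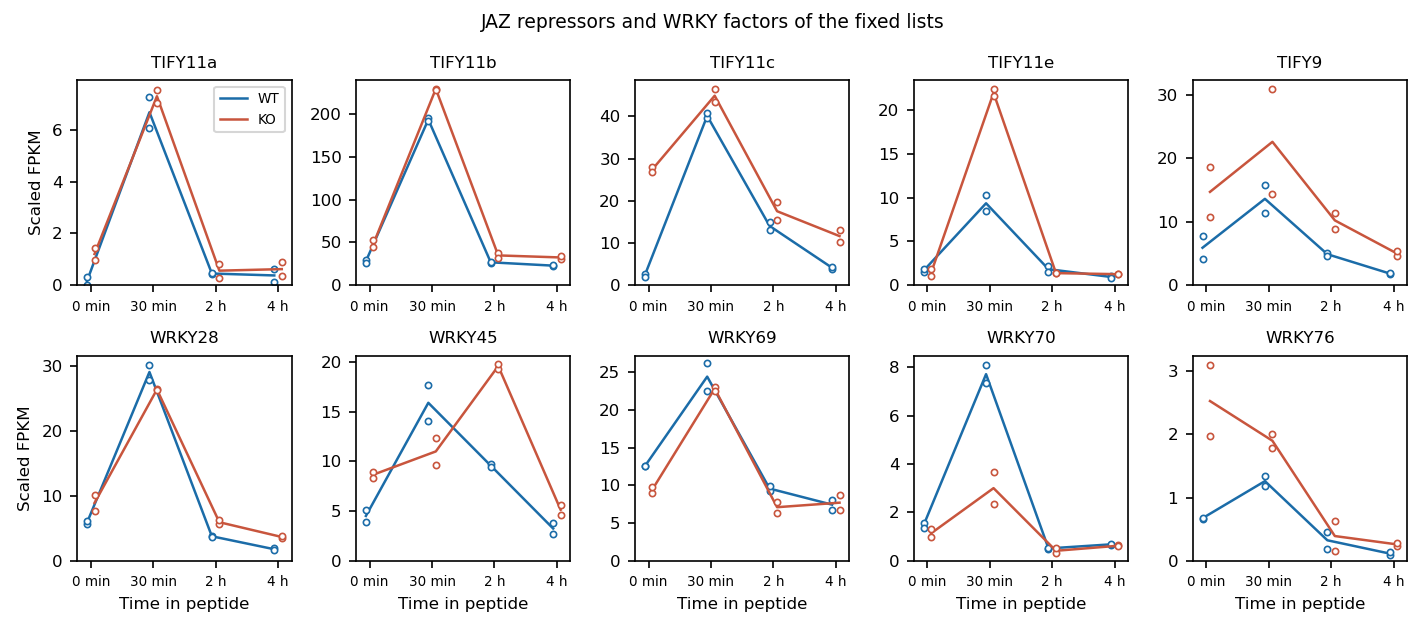
Scaled FPKM (vertical axes, from 0, each panel on its own range) of the JAZ and WRKY loci by time in peptide, with times evenly spaced and not to scale; open points are libraries and lines join group means of WT and KO. TIFY11b went from 27.9 to 194 in WT and from 48.2 to 230 in KO at 30 min, while TIFY11c began at 2.28 in WT and 27.4 in KO.

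At 2 h in WT, TIFY11c and WRKY45 were the JAZ and WRKY loci called higher than at 0 min. TIFY11c was at 14 ± 1.4 (log2 2.2, adjusted p = 4.4e-07), and TIFY11b was at 26.6 ± 1.0 (adjusted p = 0.66). Of the 5 WRKY loci WRKY45 was at 9.57 ± 0.23, and WRKY28, WRKY70 and WRKY69 were lower. The 3 light-harvesting loci rose, with LHCB1 at 3990 ± 130 and LHCB2 at 4190 ± 110. PR4 (20.1 ± 0.041) and JIOsPR10 (27.8 ± 3.8), both jasmonate synthesis loci, CYP76M7, CYP99A3 and PCL1 were higher, while EXPA2, EXPB3, EXPB4 and CPS4 were lower. Each of these list counts was equal adjusted over the list alone. Of 13095 loci 5970 were called, 3139 higher and 2831 lower, 1101 and 754 of them by 2-fold or more. Neither list passed camera at 2 h, with adjusted p = 0.41 for both. Against the 30 min libraries, an alternative chosen after seeing the data, 3058 loci were called in WT at 2 h, and without scaling 36.1% of the called loci were higher against 52.6% with it.

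At 4 h in WT, 4 of 5 WRKY loci were lower than at 0 min, WRKY28 at 1.75 ± 0.25 (log2 -1.32, adjusted p = 5.2e-06) among them. Of the JAZ loci 3 were lower, TIFY9, TIFY11b and TIFY11e, and TIFY11c was higher at 4.09 ± 0.31. PCL1 (Os01g0971800, chromosome 1, 42874273 to 42875515), a clock gene, reached 40.2 ± 0.25 (log2 4.70, adjusted p = 3.5e-09). All 3 light-harvesting loci were higher than at 0 min, LHCB1 at 827 ± 13 and LHCB2 at 676 ± 10. All 3 pathogenesis-related loci were higher, with PR4 at 2.74 ± 0.1 and PR1b at 0.655 ± 0.015, as were both jasmonate synthesis loci, AOS2 at 20.2 ± 0.28. Among the other lists CYP76M7 was higher and CPS4, EXPA2, EXPB3 and EXPB4 lower; adjusted over the list alone ELF3 was lower too, and all other list counts were equal. Of 13095 loci 6703 were called, 3330 higher and 3373 lower, 1029 and 1150 by 2-fold or more. The WRKY list fell by camera (adjusted p = 0.046), a call that was not kept with an estimated correlation (adjusted p = 0.098 with an estimated correlation) or without scaling (adjusted p = 0.06). The JAZ list gave adjusted p = 0.63.

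In KO leaves 4 of 5 JAZ loci and 3 of 5 WRKY loci rose at 30 min, and most other loci named above were not called. The JAZ loci that rose were TIFY11b from 48.2 ± 6.0 to 230 ± 0.54 (log2 2.23, SE 0.1, adjusted p = 3.2e-07), TIFY11e (Os10g0391400, chromosome 10, 13031180 to 13032006) from 1.41 ± 0.57 to 22 ± 0.62 (log2 3.28, adjusted p = 9.5e-07), TIFY11a from 1.2 ± 0.35 to 7.31 ± 0.36 and TIFY11c from 27.4 ± 0.99 to 44.9 ± 2.2. The WRKY loci that rose were WRKY28 from 8.89 ± 1.7 to 26.4 ± 0.03, WRKY69 from 9.41 ± 0.55 to 22.8 ± 0.38 and WRKY70 from 1.13 ± 0.23 to 3 ± 0.92, while TIFY9 (adjusted p = 0.38), WRKY45 (0.29) and WRKY76 (log2 -0.27, 0.40) did not pass. LHCB1 rose from 185 ± 2.2 to 351 ± 4.9 and LHCB2 from 909 ± 1.8 to 1110 ± 16, changes of 0.92 and 0.28 on the log2 scale. AOS2, PR4 and CYP76M7 were higher by 0.80, 0.54 and 0.62, and EXPB3 fell from 8.83 ± 0.029 to 1.53 ± 0.35; neither clock locus was called. These list counts were equal adjusted over the list alone. Of 13095 loci 2040 were called, 914 higher and 1126 lower, 120 and 161 by 2-fold or more. Both lists rose by camera, JAZ with adjusted p = 1e-06 (adjusted p = 0.0018 with an estimated correlation) and WRKY with adjusted p = 0.00092 (adjusted p = 0.0096 with an estimated correlation). The KO count fell to between 1282 and 1435 when any 1 of its 4 libraries was left out and to 614 when only these 4 libraries were fitted, and without scaling 15.4% of the called loci were higher against 44.8% with it.

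At 2 h in KO, WRKY45 was higher at 19.6 ± 0.41 (log2 1.09, adjusted p = 0.0015), and WRKY76, WRKY28 and WRKY70 were lower, with WRKY69 lower as well adjusted over the list alone. TIFY11b (34.7 ± 3.5) and TIFY11c (17.5 ± 2.9) were lower than at 0 min. All 3 light-harvesting loci were higher, LHCB1 at 725 ± 15, and EXPB3 was lower at 3.24 in the 1 library that has values there, which is assumed to vary like the other groups. No tested locus of the clock, jasmonate synthesis, pathogenesis-related or phytoalexin lists was called, over all loci or adjusted over the list alone. Of 13095 loci 2552 were called, 1177 higher and 1375 lower, 222 and 200 by 2-fold or more, and camera gave adjusted p = 0.071 for both lists. The count was 738 when only the 4 libraries compared were fitted, and 3860 against the 30 min libraries, an alternative chosen after seeing the data, and without scaling 50.8% of the called loci were higher against 46.1% with it. All 12125 rows of KO 2 h replicate 1 beyond position 19174055 of chromosome 10, on chromosomes 11 and 12 and on unplaced contigs were exactly 0, and were treated as missing.

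At 4 h in KO, PCL1 rose from 0.801 ± 0.47 to 28 ± 0.78 (log2 4.04, adjusted p = 4.8e-08), and PR1b, a pathogenesis-related protein, from 0.615 ± 0.22 to 6.72 ± 0.13 (log2 2.26, adjusted p = 3.4e-06). LHCB1 (853 ± 1.4), LHCB1b (5900 ± 78) and LHCB2 (1550 ± 4.0) were higher, as were AOS2 and AOC. TIFY11b, TIFY11c and TIFY9 were lower, as were WRKY45, WRKY76 and WRKY28, and EXPB3 fell to 0.588 ± 0.14. Adjusted over the list alone 1 more WRKY locus was lower, and the other list counts were equal. Of the 8 phytoalexin loci listed, none of the 3 tested was called. Of 13095 loci 3665 were called, 1869 higher and 1796 lower, 472 and 311 by 2-fold or more. Both lists fell by camera, JAZ with adjusted p = 0.011 (adjusted p = 0.031 with an estimated correlation) and WRKY with adjusted p = 0.0042 (adjusted p = 0.028 with an estimated correlation).

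**Figure D3:**
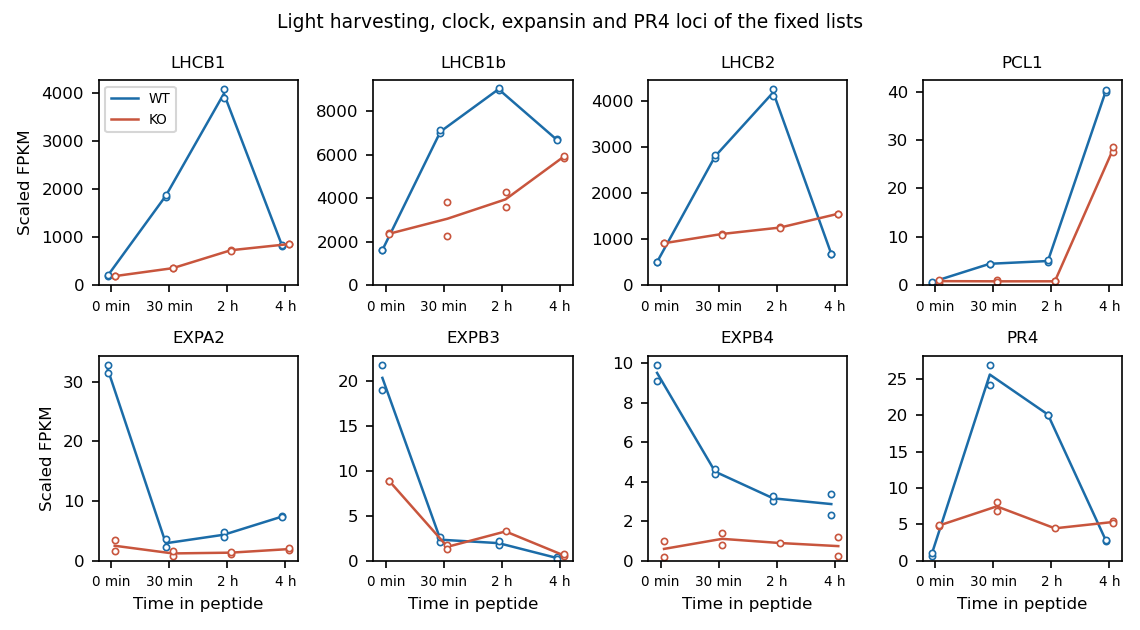
Scaled FPKM (vertical axes, from 0, each panel on its own range) of light-harvesting, clock, expansin and PR4 loci by time in peptide, with times evenly spaced and not to scale; open points are libraries and lines join group means of WT and KO. LHCB1 went from 195 to 3990 at 2 h in WT and from 185 to 725 in KO, and PCL1 reached 40.2 in WT and 28 in KO at 4 h.

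The genotypes differed at 0 min, where the WT libraries stood apart from all other groups. KO 0 min had a mean r of 0.871 with WT 0 min and of 0.947 with WT 30 min. The differences below therefore cannot be told apart from the state of the WT leaves at 0 min. TIFY11c was at 27.4 ± 0.99 in KO and 2.28 ± 0.51 in WT (log2 3.13, SE 0.14, adjusted p = 2.1e-08), and 4 of 5 JAZ loci were higher in KO. All 3 pathogenesis-related loci were higher in KO, PR4 at 4.81 ± 0.079 against 0.884 ± 0.29 and JIOsPR10 at 31.4 ± 0.95 against 12.7 ± 0.48. Of the WRKY loci 3 were higher and WRKY69 was lower, CYP76M7 and CYP99A3 were higher, and LHCB1b and LHCB2 were higher. Expansins were lower in KO at 3 of 4 loci: EXPA2 was at 2.49 ± 1.3 against 32.1 ± 0.95 (log2 -3.30, adjusted p = 1.3e-06), EXPB4 at 0.591 ± 0.58 against 9.5 ± 0.55 and EXPB3 at 8.83 ± 0.029 against 20.3 ± 1.9. ELF3 was lower in KO and AOC higher; adjusted over the list alone AOS2 was lower too, and the other list counts were equal. Of 13095 loci 6871 were called, 3555 higher in KO and 3316 lower, 1255 and 1064 by 2-fold or more. Neither list passed camera, with adjusted p = 0.082 for JAZ and 0.41 for WRKY.

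At 30 min the light-harvesting loci were lower in KO, LHCB1 at 351 ± 4.9 against 1860 ± 32 (log2 -2.40, SE 0.037, adjusted p = 3.5e-11) and LHCB2 at 1110 ± 16 against 2800 ± 52. PR4 was lower at 7.46 ± 0.86 against 25.6 ± 1.9, AOS2 and AOC were lower by 0.90 and 0.51 on the log2 scale, and PCL1 was lower at 0.761 ± 0.33 against 4.39 ± 0.058. TIFY11e was higher in KO at 22 ± 0.62 against 9.36 ± 1.3 and was the 1 JAZ locus called, while TIFY11b was at 230 ± 0.54 against 194 ± 3.1 (adjusted p = 0.087). WRKY70 was lower in KO, as were CYP76M7, CYP99A3, EXPA2, EXPB4 and EXPB7, and CPS4 was higher. Adjusted over the list alone 1 more expansin and 1 more WRKY locus were lower, and the other list counts were equal. Of 13095 loci 4520 were called, 1997 higher and 2523 lower, 262 and 602 by 2-fold or more, and with quantile normalization 53.2% of the called loci were higher against 44.2%. Camera gave adjusted p = 0.13 for JAZ and 0.31 for WRKY.

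At 2 h LHCB1 was at 725 ± 15 in KO against 3990 ± 130 in WT (log2 -2.46, adjusted p = 2.8e-11), LHCB2 at 1250 ± 28 against 4190 ± 110 and LHCB1b at 3940 ± 460 against 9010 ± 79. PR4 was at 4.44 in the 1 KO library with a value there, against 20.1 ± 0.041 (log2 -1.95, adjusted p = 6.6e-06). That lone library, which also gives the KO levels of EXPB3 and EXPB4 at 2 h, is assumed to vary like the other groups. AOS2, AOC, PCL1, CYP76M7, CYP99A3, EXPA2, EXPB4 and WRKY69 were lower in KO, and TIFY11b, WRKY45, WRKY28 and CPS4 were higher. Adjusted over the list alone EXPB3 was higher, EXPB7 lower and PSKR1 lower as well. Of 13095 loci 4504 were called, 2078 higher and 2426 lower, 400 and 550 by 2-fold or more, and camera gave adjusted p = 0.41 for both lists. The count was 2776 when only the 4 libraries compared were fitted, and without scaling 65.0% of the called loci were higher against 46.1% with it. With quantile normalization the difference of LHCB1b at 2 h was 0.

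At 4 h PR1b was at 6.72 ± 0.13 in KO against 0.655 ± 0.015 (log2 2.22, SE 0.17, adjusted p = 6.4e-06), and PR4 and JIOsPR10 were higher too. TIFY11c was at 11.6 ± 1.9 against 4.09 ± 0.31 (log2 1.30, adjusted p = 0.00011) and TIFY11b at 32.3 ± 2.9 against 22.7 ± 1.3, and 1 more JAZ locus was higher adjusted over the list alone. WRKY28 was higher in KO, with 1 more WRKY locus adjusted over the list alone. LHCB2 was higher at 1550 ± 4.0 against 676 ± 10, and LHCB1 was at 853 ± 1.4 against 827 ± 13 (adjusted p = 0.48). AOC and CYP99A3 were higher and AOS2, EXPA2 and EXPB4 lower; PCL1 was at 28 ± 0.78 against 40.2 ± 0.25 (adjusted p = 0.064) and passed adjusted over the list alone. Of 13095 loci 2599 were called, 1546 higher and 1053 lower, 352 and 90 by 2-fold or more. The JAZ list was higher in KO by camera (adjusted p = 0.02), a call not kept with an estimated correlation (adjusted p = 0.061 with an estimated correlation), and the WRKY list gave adjusted p = 0.15. The count was 1511 when only the 4 libraries compared were fitted, and with quantile normalization 48.6% of the called loci were higher against 59.5%.

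Averaged over the 4 times, all 5 JAZ loci were higher in KO, TIFY11c by 1.22 (SE 0.072, adjusted p = 2.2e-07) and TIFY9 by 0.95 on the log2 scale, and 5 were also adjusted over the list alone. This average includes the WT 0 min libraries. TIFY11c differed by 3.13 at 0 min and by 0.16, 0.3 and 1.3 at 30 min, 2 h and 4 h. TIFY11a was called at 0 min only. TIFY11e was called at 30 min only (1.16), with -0.16 at 0 min and -0.24 at 2 h. TIFY11a, TIFY11b, TIFY11c and TIFY9 had positive differences at each time. PR1b and JIOsPR10 were higher. PR4 was lower on average, though higher in KO at 0 min (4.81 against 0.884) and 4 h (5.31 against 2.74). The 3 light-harvesting loci were lower, LHCB1 by -1.22 (adjusted p = 9.8e-12), as were EXPA2 (-1.71, adjusted p = 1.3e-06), EXPB4, EXPB7, AOS2 and PCL1. The light-harvesting average covers a change of sign: all 3 loci were lower in KO at 30 min and 2 h only. LHCB1b and LHCB2 were higher in KO at 0 min, and LHCB2 was higher at 4 h (1550 against 676). WRKY45, WRKY76 and WRKY28 were higher and WRKY70 and WRKY69 lower, and CPS4 was higher. Adjusted over the list alone ELF3 was lower too, and the other list counts were equal. Outside the naming rule, and chosen after their values were seen, Os02g0252400 was at 34.2 ± 2.4, 28.7 ± 2.1, 29.5 ± 2.1 and 20.7 ± 2.5 in KO from 0 min to 4 h, against 1.04 ± 0.35 and 0.0336 ± 0.048 in WT at 0 and 30 min and values listed at 0 at 2 h and 4 h. Os08g0231400 was at 0.0181 ± 0.026, 0.346 ± 0.12, 0.123 ± 0.083 and 27.1 ± 0.8 in KO, against 114 ± 0.37, 17.4 ± 0.2, 9.21 ± 0.34 and 102 ± 0.64 in WT.

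Over all times 6181 of 13095 loci were called, 3099 higher in KO and 3082 lower, 229 and 185 by 2-fold or more. At all 4 times 210 loci were called higher in KO and 199 lower, where independent calls at the same rates would give 10.2 and 9.52, and 45 and 19 of them differed by 2-fold or more at each time. That expectation gives each locus the same chance of a call, though loci differ in level and spread, so an excess over it is no test. The JAZ list was higher in KO by camera (adjusted p = 0.01, and adjusted p = 0.042 with an estimated correlation), and the WRKY list gave adjusted p = 0.47. With the 8 group means as the units of the test, an alternative chosen after seeing the data that treats the 4 times as replicates, 31 loci were called, 27 higher and 4 lower. No locus of the fixed lists was among them, so each call over all times of a list locus named above was lost, as was that of Os08g0231400, while Os02g0252400 kept its call.

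**Figure D4:**
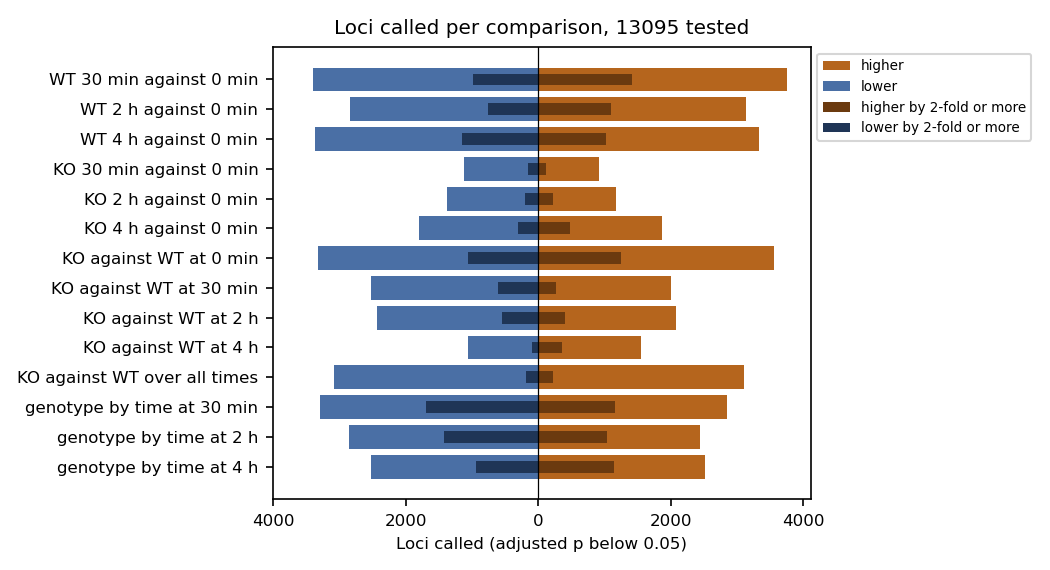
Number of loci called per comparison (horizontal axis; to the right higher, to the left lower; narrow dark bars are changes of 2-fold or more), of 13095 tested. The changes from 0 min number 5970 to 7146 in WT and 2040 to 3665 in KO.

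The genotype by time terms compare the change from 0 min in KO with that in WT. At 30 min the change of all 3 light-harvesting loci was smaller in KO, with terms of -2.33 for LHCB1 (SE 0.053, adjusted p = 2.6e-10), -2.20 for LHCB2 and -1.81 for LHCB1b. PR4 (-3.29, adjusted p = 2.3e-07), JIOsPR10, AOS2, AOC, CYP76M7, CYP99A3 and PCL1 also had negative terms. JIOsPR10 began at 31.4 in KO against 12.7 in WT, and its level was not called different between the genotypes at 30 min or 2 h. PR4 began at 4.81 in KO against 0.884 in WT and was lower in KO at 30 min and 2 h. TIFY11c (-2.97, adjusted p = 7.9e-07) and TIFY11b (-0.52) rose less in KO and TIFY11e (1.31, adjusted p = 0.0012) rose more, and WRKY45, WRKY28 and WRKY70 rose less or were not called in KO. EXPA2, EXPB3 and EXPB4 fell less or were not called in KO, with terms of 2.47, 0.72 and 1.37, and ELF3 and CPS4 had positive terms. At 0 min EXPA2 was at 2.49 in KO against 32.1 in WT and EXPB4 at 0.591 against 9.5. EXPA2 and EXPB4 thus had less room to fall in KO. EXPB3 also began lower in KO, at 8.83 against 20.3. At 2 h the terms were negative for LHCB1, LHCB1b, LHCB2, PR4, JIOsPR10, TIFY11b, TIFY11c, AOS2, AOC, WRKY76, CYP76M7, CYP99A3, PCL1 and PSKR1 and positive for EXPA2, EXPB3, EXPB4 and CPS4; those of PR4, EXPB3 and EXPB4 rest on 1 KO library at 2 h. With quantile normalization the terms at 2 h were -1.26 for LHCB1, -0.26 for LHCB1b and -1.64 for LHCB2, against -2.38, -1.75 and -2.60. At 4 h PR1b (1.78, adjusted p = 0.00016), LHCB2, ELF3, EXPA2, EXPB3 and EXPB4 had positive terms, and TIFY11c, AOS2, WRKY76, JIOsPR10, PR4, CYP76M7 and LHCB1b negative ones. The levels of JIOsPR10 (30.4 against 17) and PR4 (5.31 against 2.74) were higher in KO at 4 h despite these negative terms. Adjusted over the list alone, 1 more WRKY locus and 1 more expansin had a negative term at 30 min, and at 4 h PCL1 a negative and LHCB1 a positive one. TIFY11c, with negative terms at all 3 times, differed by 3.13 between the genotypes at 0 min and by 0.16 (adjusted p = 0.44) at 30 min.

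Genotype by time terms were called at 6145 loci at 30 min (2847 positive, 3298 negative), 5298 at 2 h (2446 and 2852) and 5036 at 4 h (2511 and 2525). Camera called neither list at any time: adjusted p was 0.31 for both at 30 min, 0.21 for JAZ and 0.87 for WRKY at 2 h, and 0.52 and 0.94 at 4 h. At 4 h the WRKY list had a median term of 0.17, a mean of -0.07 and a camera direction of up, and at 2 h a median of 0.02, a mean of -0.15 and a direction of down. Against the 30 min libraries, chosen as the baseline after seeing the data, 3491 loci had a term at 2 h and 3106 at 4 h; without scaling 62.6% of the terms at 2 h were positive against 46.2% with it, and with quantile normalization 53.5% of those at 30 min against 46.3%.

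The changes of WT and KO from their own 0 min libraries were compared locus by locus. For the JAZ and WRKY loci at 30 min the changes had the same sign in both genotypes at 9 of the 10 tested, WRKY76 being the exception with 0.44 and -0.27, neither called. Across all 13095 loci Pearson's r between the changes was -0.0887 at 30 min, -0.135 at 2 h and 0.315 at 4 h, and Spearman's rho was -0.128, -0.138 and 0.231. These are correlations across loci, which are not independent replicates, and no p is given. At 30 min 374 loci were called higher in both genotypes, 227 lower in both and 943 in opposite directions, where independent calls at the same rates would give 262, 292 and 559. At 2 h the numbers were 408, 270 and 1098 (282, 297 and 584 if independent), and at 4 h 1046, 763 and 791 (475, 463 and 938). The expected numbers again give each locus the same chance of a call. With the 30 min libraries as the baseline, chosen after seeing the data, r was 0.153 at 2 h and 0.458 at 4 h. Every change of a genotype is taken from the same 2 libraries at 0 min.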

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

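The tests given here were chosen only after the results they concern had been seen, except the genotype by time terms and the regrouping of single libraries.

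The change from 0 min differed between KO and WT, by the test of the difference itself, at 6145 loci at 30 min, 5298 at 2 h and 5036 at 4 h. A negative value is a smaller rise or a larger fall in KO than in WT, or a fall in KO where WT rose, on the log2 scale. At 30 min the terms of the named loci were -2.33 for LHCB1, -1.81 for LHCB1b, -2.20 for LHCB2, -3.29 for PR4, -1.48 for JIOsPR10, -0.57 for AOS2, -0.98 for AOC, -1.79 for PCL1 and 1.54 for ELF3. They were -0.52 for TIFY11b, -2.97 for TIFY11c, 1.31 for TIFY11e, -1.31 for WRKY45, -0.65 for WRKY28, -0.93 for WRKY70, 0.72 for CPS4, -1.68 for CYP76M7, -2.07 for CYP99A3, 2.47 for EXPA2, 0.72 for EXPB3 and 1.37 for EXPB4.

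At 2 h the terms were -2.38 for LHCB1, -1.75 for LHCB1b, -2.60 for LHCB2, -3.59 for PR4, -1.17 for JIOsPR10, -0.65 for AOS2, -0.72 for AOC, -1.92 for PCL1, -0.70 for PSKR1, -0.40 for TIFY11b and -2.83 for TIFY11c. They were -1 for WRKY76, 0.76 for CPS4, -1.58 for CYP76M7, -1.67 for CYP99A3, 2.10 for EXPA2, 1.65 for EXPB3 and 1.64 for EXPB4. With quantile normalization the light-harvesting terms at 2 h shrank to -1.26 for LHCB1, -0.26 for LHCB1b and -1.64 for LHCB2, and at 30 min that of LHCB1b was -1.05; the term of LHCB1b at 2 h lost its call. At 4 h they were 1.04 for ELF3, -1.82 for TIFY11c, -0.80 for AOS2, -0.88 for WRKY76, 1.78 for PR1b, -0.43 for JIOsPR10, -0.88 for PR4, -0.83 for CYP76M7, -0.73 for LHCB1b, 0.33 for LHCB2, 1.78 for EXPA2, 1.41 for EXPB3 and 1.57 for EXPB4.

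The WT 0 min libraries stand apart from the rest, and all of these terms rest on them. The scaling of the libraries is argued against, since 7009 loci were called for KO against WT at 0 min without it and 6871 with it. A KO sample under a WT label, or KO RNA mixed into WT, is argued against by the 13 loci that were on in every KO library with a value (1 lies in the part missing from KO 2 h replicate 1) and off in the WT libraries from 30 min on: at 11 of them both WT 0 min libraries lay below each of these, and the share of the KO level ran from 0 at 5 loci to 63.1%, with 10 loci under 0.1 of the highest, where mixing alone would give 1 share to all, though 6 of the 13 had a WT 0 min mean of at least 0.5. The state of the WT leaves at 0 min (hour, light, handling or plants) stays open beside a difference by genotype: with the 30 min libraries as the baseline fewer loci were called at 2 h in WT (3058) than in KO (3860), as a passing state would give, but more at 4 h (4843 and 4176). It cannot be told apart from the genotype, because each genotype was sampled at 0 min in 1 group only.

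The 2 libraries of each group lay close together: at loci with at least 1000 fragments they differed by a median of 3.1% to 3.7%. A library deposited under both titles is argued against, since the median squared difference within a pair was at least 1.81 times that of counting noise. That both came from the same leaves or RNA stays possible. Against counting noise, the squared differences were no larger at 1000 or more fragments than at 30 to 100, the median ratio over the 8 pairs being 0.952. At the depths between they were larger than at 30 to 100 in most pairs, as with 2.41 and 2.38 against 1.86 for WT 0 min. No pair known to come from separate plants was at hand for comparison. If both libraries of a group came from the same leaves or RNA, the p-values in the text leave out the spread between plants. No biological explanation was tested.

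In KO 2 h replicate 1 the table holds no value above 0 for the last part of chromosome 10 and for chromosomes 11 and 12. A loss of these parts in the KO plants is argued against, since they held 13.5% of the joined FPKM in the other KO 2 h library. A file that ended early before the values were made is consistent with complete values ahead of the gap: at most 0.655% of loci on any of chromosomes 1 to 9 were at 0 there, against up to 1.04% in other libraries.

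For KO against WT over all times, regrouping the 16 libraries within each time gave as many loci in 1 of 100 splits, the real one, with 2494 loci against at most 63 in another. These counts come from a fit of time and 1 split, not from the group means behind the 6181 loci of the report. Each other split drawn parts the close libraries of at least 1 group, while the real one keeps them together, which alone favours the real one. The test therefore says nothing of the spread between plants or samplings, and no conclusion on chance is drawn from it. Regrouping whole groups allows 8 splits, too few for a share under 0.05, with 2494 loci for the real one and at most 1012 for another, the split that exchanges the genotypes at 30 min. The split that exchanges them at 30 min, 2 h and 4 h gave 833, so groupings other than the real one also exceed 63.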

How the results depend on the processing

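Alternatives concerning the 30 min baseline, the overlap used in joining, the zeros of the missing part, the group means and the fit without the 0 min libraries were chosen only after the results had been seen. Of 14 counts of loci, those not named here stayed within 1.5 times under every alternative run, as did KO against WT over all times without the 0 min libraries, at 4669. Fitted with only the libraries compared, the counts were 614 for KO 30 min (2040 with all libraries), 738 for KO 2 h (2552), 2776 for KO against WT at 2 h (4504) and 1511 at 4 h (2599), where fewer libraries estimate the spread. With 1 library left out, whose lone partner is assumed to vary like the other groups, KO 30 min ranged from 1282 to 1435. The side with more calls depends on the scaling: with quantile normalization it changed in every comparison except KO 2 h, KO against WT at 2 h and genotype by time at 4 h, and in these 3 it changed with FPKM as deposited, where 50.8%, 65.0% and 53.2% were higher (46.1%, 46.1% and 49.9% as planned). With group means as the units KO against WT over all times gave 31, none of them a list locus, since the 4 times then count as replicates.

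With the 30 min libraries as the baseline the counts were 3058 for WT 2 h (5970), 3860 for KO 2 h (2552), and 3491 and 3106 for genotype by time at 2 h and 4 h (5298 and 5036). The correlation of WT and KO changes then turned from -0.135 to 0.153 at 2 h and went from 0.315 to 0.458 at 4 h; the cause was not tested. At 30 min it was -0.1 as deposited, -0.076 with an overlap of 0.5 and -0.089 to -0.075 with 1 library left out. At 2 h it was -0.118 with the zeros kept and -0.135 to -0.118 with 1 library left out, and at 4 h 0.336 with a pseudocount of 0.1 and 0.286 to 0.318 with 1 library left out.

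Camera lost 2 calls with an estimated correlation, WRKY in WT at 4 h (adjusted p = 0.098) and JAZ for KO against WT at 4 h (adjusted p = 0.061), and the former also as deposited (adjusted p = 0.06). The estimates, -0.14 for JAZ and -0.039 for WRKY, lay below the preset 0.01, so a stronger correlation was not what cost these calls. Fry, which does not compare a list with other loci, passed in most comparisons where camera did not, the exceptions being JAZ in WT at 4 h (adjusted p = 0.095) and WRKY for genotype by time at 2 h (0.41) and 4 h (0.98). For JAZ its adjusted p was 8.9e-05 for WT 2 h, 0.00017 for KO 2 h, 3.5e-08, 0.00033 and 0.017 for KO against WT at 0 min, 30 min and 2 h, and 2.9e-05, 5.9e-06 and 0.00059 for genotype by time at 30 min, 2 h and 4 h. For WRKY it was 0.0038 for WT 2 h, 0.00043 for KO 2 h, 0.0013, 0.0023, 0.017 and 0.0029 for KO against WT at 0 min, 30 min, 2 h and 4 h, 0.0034 over all times and 0.00024 for genotype by time at 30 min.

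Of 245 called changes of named loci, refitted 4056 times under all settings but group means, the changed baseline and the fit without the 0 min libraries, 3733 fits kept direction and call, 322 kept the direction without the call, and in 1, quantile normalization, LHCB1b for KO against WT at 2 h went to 0, where the cause was not tested. Replicate numbers do not pair libraries between groups: the differences between the 2 libraries of a group correlated between 28 pairs of groups from -0.267 to 0.309, with a median of 0.008. With the number as a block WT 30 min gave 7060 loci, and 240 of the 245 named changes kept their call. No alternative lacked a fit, though library weights give the 2 libraries of a group equal weight, and for KO against WT over all times the libraries compared are all 16. Some calls depend on the pseudocount: with 0.1, 16 of the 245 named changes lost their call.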

Other observations

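No test was run on the values in this part, and the loci were picked only after their values had been seen.

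Some list loci could not enter the comparisons because some library held more than 1 row or a longer row there. Their deposited, unscaled FPKM are given for the row that overlaps the locus by at least 0.8 of both lengths. Where more than 1 row did, the highest FPKM was taken. Reads of such a locus may lie in other rows, so a low value here may understate its level. FKF1 (Os11g0547000, chromosome 11, 20182477 to 20187327), a blue-light receptor of the flowering clock, was at 0.267 ± 0.099, 2.23 ± 0.23, 6.08 ± 0.21 and 20.9 ± 2.1 (SD, n = 2) in WT at 0 min, 30 min, 2 h and 4 h. In KO it was at 0.847 ± 0.033, 1.21 ± 0.022, 3.42 (1 library) and 12.1 ± 0.098. FKF1 and the clock locus PCL1 thus were each at their highest group mean at 4 h in both genotypes. LHCA1 (Os06g0320500, chromosome 6, 12452708 to 12454049), an antenna protein of photosystem I, was at 766 ± 12, 1562 ± 7.8, 2838 ± 47 and 984 ± 6.7 in WT and 520 ± 16, 467 ± 6.7, 952 ± 21 and 1451 ± 66 in KO, with its highest mean at 2 h in WT and at 4 h in KO.

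The expansin EXPA4 (Os05g0477600, chromosome 5, 23495654 to 23497572) was at 10 ± 0.83 in WT at 0 min and at or under 0.213 in the means of the other 7 groups. WRKY71 (Os02g0181300, chromosome 2, 4542938 to 4544874) was at 146 ± 1.4, 261 ± 15, 146 ± 4.4 and 125 ± 3.1 in WT, and at 168 (1 library), 187 ± 1.7, 178 (1 library) and 142 ± 9.6 in KO, with its highest mean at 30 min in both. PBZ1 (Os12g0555500, chromosome 12, 22600049 to 22601182), a pathogenesis-related protein, was at 10 ± 1.7, 38.8 (1 library), 50.5 ± 6.1 and 17 ± 1.2 in WT, and at 22.9 ± 1.2, 32.1 ± 2.6 and 28.8 (1 library) in KO at 0 min, 30 min and 2 h, with no matching row in KO at 4 h. KSL7 (Os02g0570400) of the phytoalexin list was at 0.0237 ± 0.017, 0.948 ± 0.14, 0.0497 ± 0.07 and 6.38 (1 library) in WT. In KO KSL7 was at 0.297 ± 0.028, 0.393 ± 0.043, 0.601 ± 0.07 and 3.68 ± 1.4, so its highest mean was at 4 h in both genotypes. At 13 loci every KO library with a value was at 2 or more (at 1 of them, Os11g0437600, KO 2 h replicate 1 has no value) while every WT library from 30 min on was below 0.1, and no locus showed the reverse; at 5 of the 13 both WT 0 min libraries were listed at 0, and at 6 their mean was at least 0.5.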
